A study of Mus musculus with 12 samples.

How the data were processed

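RNA was sequenced from 12 samples of mouse (C57BL/6) hypothalamic cells. Hypothalami of embryonic day 18 were dissociated, a virus was added at a multiplicity of infection of 10, and the cells were grown as neurospheres, floating balls of neural cells, in low-adherence wells. An adeno-associated virus carried the mCherry reporter for Hcrt (hypocretin, also called orexin) cells, and a lentivirus carried the EGFP reporter for MCH (melanin-concentrating hormone, gene Pmch) cells. Basic fibroblast growth factor at 10 ng/ml was added a day later, and after a week the cells were dissociated and sorted into reporter-positive and reporter-negative cells. The sort gave 4 groups of 3 samples: mCherry-positive, mCherry-negative, EGFP-positive and EGFP-negative. Per the labels, cDNA was made with SMART-Seq v4 from 0.8 ng of total RNA for the Hcrt sort and from 2 ng for the MCH sort, with 11 cycles of PCR. Libraries were then made from 150 pg of cDNA with Nextera XT.

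The deposited files hold raw counts, whole numbers of reads per Ensembl gene, in 1 file per sample and with no normalization by the authors. The authors' processing notes name cutadapt 1.8, STAR 2.5.2b and HTSeq 0.6.1 on genome build GRCm38. The settings, the annotation release and the strand setting of the counting were not given in the sources used here. The last 5 entries of each file are HTSeq's summary of reads assigned to no gene and were left out of the library sizes. Of 48709 gene identifiers, 48349 matched the GENCODE M21 annotation used here for symbols and GRCm38 positions, and the 360 others took at most 0.0279% of any library's gene reads.

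Libraries held 16.3 to 32.9 M (megareads) in genes, and 31.4% to 38.2% of all counted reads stood in the entries that name no gene. A count of 0 in a library allows a level of up to 3 counts as a one-sided limit at 95%. Intervals of single counts are two-sided exact Poisson intervals at 95%, whose upper end at a count of 0 is higher than that limit. PCR reads without molecular identifiers are not independent molecules, so intervals and these limits cover counting error only. Between replicates of a group, the chi-square per degree of freedom over genes was 6.54 to 97.0, well above counting error alone, so no pair of files was a copy or a technical split of 1 library. The labels do not say whether replicates are separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

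Each reporter was analysed on its own 6 samples with edgeR 4.0.16 in R 4.3.3: TMM scaling factors, the filterByExpr filter (minimum count 10, minimum total 15), a fit with group as the only term, and the quasi-likelihood test with Benjamini-Hochberg adjustment, with genes called at an adjusted p under 0.05. The difference between both effects, mCherry effect minus EGFP effect, was tested in 1 fit of all 12 samples. That fit takes 1 spread per gene for both sorts. Fitted apart, the common coefficient of variation between replicates was 0.382 for mCherry and 0.189 for EGFP, against 0.313 in the shared fit. Adjusted p of the difference depend on this shared spread. Group means are TMM-scaled CPM (counts scaled to a megaread in genes) from the fit named. Levels of single libraries, and all levels of Hcrt and Pmch, are plain CPM without TMM scaling and are not on the scale of the other group means. For Hcrt and Pmch they were compared with a 2-sided exact permutation test and with the exact binomial interval of the ratio of their summed counts. Log2 fold changes are given with their standard error (SE) and CPM with the standard deviation (SD) over 3 samples. The SE was derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic.

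In each comparison 26 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 26 lists. The lists cover Hcrt and MCH neuron markers, other neuronal and hypothalamic genes, glial, vascular and immune cell markers, and stress, metabolic and mitochondrial genes. Alternatives for the lists were an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction. One listed symbol, Kiss1, was not found among the annotated identifiers. Within a list, members called after adjustment over all genes and after adjustment over the list alone are both given.

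The genes named in the text followed a fixed rule. Hcrt and Pmch are always given. Per reporter, the text names up to 8 rises and 8 falls of largest log2 fold change among called genes with a mean of at least 5 CPM, a symbol that is not a clone or predicted-gene name, and no overlap between positive and negative samples. For the difference it names up to 6 in each direction without the overlap condition. Per list it names up to 4 called members of smallest adjusted p, or up to 2 members of highest CPM where none was called. The comparisons, lists, naming rule and alternatives were chosen before the data were examined. The list tests for the difference, the DESeq2 and limma-voom counts without single libraries, and the ratios of Hcrt and Pmch rates without single libraries were added after seeing the data. Genes outside this rule, such as members that went against the direction of their list or genes shared by both comparisons, were chosen after their values were seen. Some genes that the rule picks are not reported here, and lists are counted with them.

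The tests were tried on simulated data with the same depth and 200 changed genes among 16845 (mCherry), 15954 (EGFP) and 17571 (difference). Spread followed the fitted trend over expression level, without each gene's own spread or single outlying libraries. Changed genes were drawn only from those above a minimum mean count. The rates below therefore need not hold for the real data. At a 2-fold change the test recovered 34.3%, 71.6% and 13.4% of changed genes, and at 4-fold 75.8%, 98.5% and 71.2%. Of the genes it called, 8.43%, 7.19% and 0% were false. Alternatives tried were the replicate number as a block, DESeq2 size factors, no scaling beyond library size, no low-count filter beyond 1 count, a stricter filter of at least 5 CPM in at least 3 samples, DESeq2 1.42.0, limma-voom, 1 fit of all 12 samples, an adjusted p under 0.01, removal of mitochondrially encoded genes, and leaving out each library in turn. Across genes, residuals of positive and negative samples with the same number correlated at 0.126, -0.0205 and 0.0327 for mCherry and at 0.169, 9.48e-04 and 0.0656 for EGFP. Not every pair of the same number reached 0.1 in either sort, the limit set for treating the numbers as pairs, and the labels do not say whether they are. The block was therefore used only as an alternative, and small correlations like these do not exclude a shared sort. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.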

Results

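Gene expression was measured in 12 libraries from sorted neurosphere cells of embryonic mouse hypothalamus, 3 in each of 4 groups: mCherry-positive and mCherry-negative cells from the Hcrt reporter, and EGFP-positive and EGFP-negative cells from the MCH reporter. In replicate order, reads in genes numbered 24.5, 31.6 and 32.9 M (megareads) in mCherry-positive libraries and 30.4, 32.6 and 21.7 M in mCherry-negative libraries. They numbered 17.0, 26.9 and 30.9 M in EGFP-positive libraries and 24.7, 25.8 and 16.3 M in EGFP-negative libraries. The mitochondrial share of gene reads was higher in mCherry-positive libraries (1.06% to 1.54%) than in mCherry-negative libraries (0.805% to 0.953%). It was lower in EGFP-positive libraries (0.766% to 0.872%) than in EGFP-negative libraries (1.16% to 1.36%). For every 100 gene reads, 5.51 to 6.93 reads fell outside annotated features in EGFP-positive libraries and 8.58 to 9.95 in EGFP-negative libraries. In mCherry-positive libraries the value was 12.6 to 16.2, and in mCherry-negative libraries 9.19 to 15.9. On log CPM the first component held 25.8% of the variance and the second 19.7%, and the first separated all EGFP libraries from all mCherry libraries. It also set EGFP-positive libraries (scores 65.7 to 75.9) apart from EGFP-negative libraries (9.85 to 13.9), with mCherry libraries at -77.6 to -11.5. The second put mCherry-positive libraries at 48.4 to 69.8, mCherry-negative libraries at -88.6 to -2.30 and EGFP libraries at -27.3 to 11.5. The mCherry-negative replicate 3 had the lowest score on both.

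The first question was whether each sort enriched the transcript its reporter stands for. Pmch, the gene of melanin-concentrating hormone, was higher in EGFP-positive cells, at 17.2 ± 0.769 CPM (SD, n = 3), than in EGFP-negative cells, at 4.68 ± 0.587 CPM (SD, n = 3). Hcrt, the gene of the hypocretin peptides, stood near the detection limit in every group, with 0.228 ± 0.175 CPM (SD, n = 3) in mCherry-positive cells and 0.139 ± 0.0996 CPM (SD, n = 3) in mCherry-negative cells. Pmch was also low in the mCherry sort, at 0.257 CPM in positive and 0.149 CPM in negative cells, and Hcrt was low in the EGFP sort, at 0.0711 and 0.100 CPM.

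Hcrt (ENSMUSG00000045471, GRCm38 chromosome 11, 100761069 to 100762931, minus strand) had 21 reads over the 3 mCherry-positive libraries, 3 to 14 per library, and 11 reads over the mCherry-negative libraries. The ratio of their rates was 1.82, with a 95% interval of 0.837 to 4.17, so a difference was not detectable at this depth. Without mCherry-positive replicate 3, which held 14 of the 21 reads, the ratio was 0.960 (0.316 to 2.71), and without mCherry-positive replicate 2 it was 2.41 (1.08 to 5.66). The exact permutation test gave p = 0.6, and 3 against 3 samples cannot go below p = 0.1. In the highest of the 3 mCherry-positive libraries the 95% interval of the Hcrt level reached up to 0.714 CPM. Hcrt was too low for the filter of the gene-wise model. Pmch (ENSMUSG00000035383, chromosome 10, 88091072 to 88092375, plus strand) had 1296 reads in EGFP-positive and 311 in EGFP-negative libraries, a ratio of 3.72 with a 95% interval of 3.28 to 4.22. Its log2 fold change was 1.99 ± 0.18 (SE) with an adjusted p of 3.16e-04 by edgeR's quasi-likelihood test, while the exact permutation p was 0.1, the smallest possible. In the mCherry sort the exact permutation p for Pmch was 0.5, and for Hcrt in the EGFP sort it was 0.6. Of the exonic bases of Pmch, 58.1% lie inside the span of Parpbp, introns included, on the opposite strand. The share inside exons of Parpbp was not measured. Without the strand setting of the counting, it is uncertain how reads there were assigned.

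**Figure D1:**
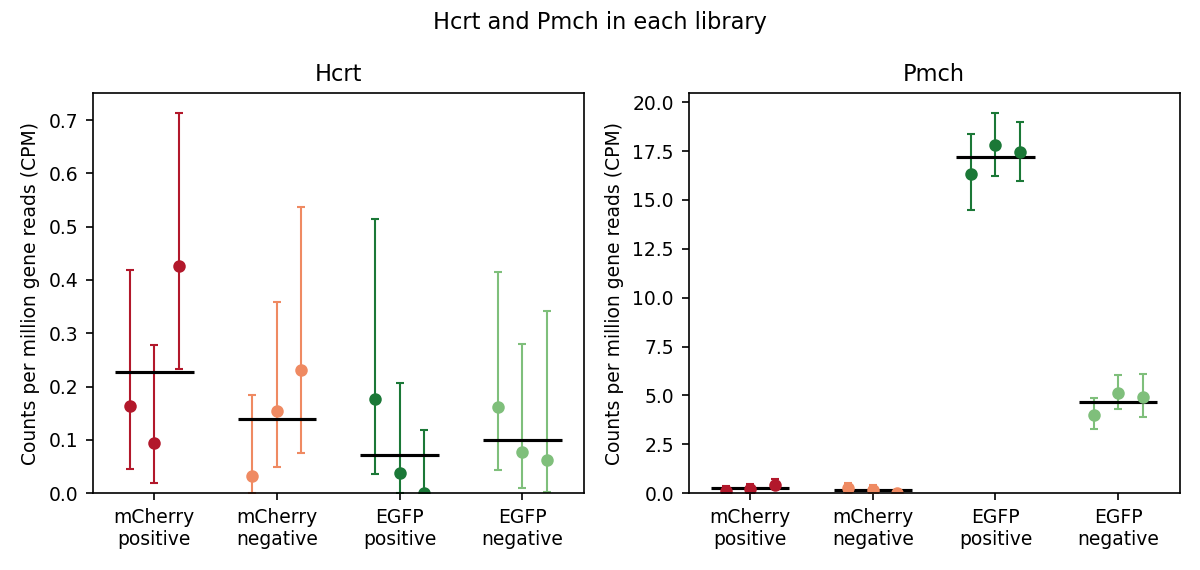
Level of Hcrt (left) and Pmch (right) in each of the 12 libraries, in CPM of gene reads on linear axes that differ between panels. Points are libraries with exact 95% Poisson intervals and black lines are means of 3; Pmch lies at 16.3 to 17.8 CPM in EGFP-positive libraries, and Hcrt stays at or under 0.426 CPM in all libraries.

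The mCherry comparison asked how cells with an active Hcrt reporter differ from cells sorted as mCherry-negative. Genes of cell division were lower in mCherry-positive cells: Cdca8, a subunit of the chromosomal passenger complex, stood at 28.9 ± 2.74 CPM (SD, n = 3) against 92.7 ± 6.88 CPM (SD, n = 3). Dlx2, a homeobox factor of the GABAergic lineage, was also lower, at 62.8 ± 17.1 against 238 ± 53.5 CPM (SD, n = 3). Gfap, the intermediate filament of astrocytes, was higher, at 3090.04 ± 623 against 1129 ± 176 CPM (SD, n = 3). The imprinted zinc-finger gene Zim1 was higher as well, at 8.45 ± 2.86 against 1.17 ± 0.515 CPM (SD, n = 3). Pomc, the precursor of melanocortins, varied so widely (2048 ± 2019 against 97.2 ± 97.9 CPM, SD, n = 3) that its difference did not pass the test, with an adjusted p of 0.218 by edgeR's quasi-likelihood test.

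Of 17369 genes tested, 94 were higher and 114 lower in mCherry-positive cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 3233 had an unadjusted p under 0.05. The balance of directions turned with the settings: 103 were higher and 99 lower with DESeq2 size factors, 188 and 155 with the replicate block, 245 and 213 with the stricter filter, 485 and 293 with no filter, 885 and 591 with DESeq2, and 125 and 87 without mCherry-positive replicate 1. The 8 named rises were Spint1, a serine protease inhibitor (log2 fold change 3.55 ± 0.59 SE), Arhgap36 (3.29), Scn9a, a voltage-gated sodium channel (2.97), Frzb, a secreted Wnt antagonist (2.79 ± 0.30 SE), Crb1 (2.78), Cdkl4 (2.74), Atp13a4 (2.62) and Mal2 (2.55). The 8 named falls were Dlx2 (-1.92 ± 0.25 SE), the kinetochore gene Spc24 (-1.85), Igfbpl1 (-1.77), the exonuclease gene Exo1 (-1.75), the Notch ligand Dll3 (-1.73), Troap (-1.73), the spindle checkpoint kinase Ttk (-1.72) and the kinetochore gene Ndc80 (-1.70). All 3 positive libraries lay beyond all 3 negative libraries in these 16 genes, as the naming rule requires. On GRCm38, Spint1 (ENSMUSG00000027315) lies on chromosome 2 from 119237362 to 119249527, Frzb (ENSMUSG00000027004) on chromosome 2 from 80411970 to 80447625, and Dlx2 (ENSMUSG00000023391) on chromosome 2 from 71543408 to 71546754.

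Among 40 cell cycle genes, 24 fell in mCherry-positive cells (39 adjusted over the list alone), with a median log2 fold change of -1.25. The falls included Cdca8 (-1.68 ± 0.18 SE), Ube2c (-1.64), Cdc20 (-1.54) and Cdk1 (-1.52 ± 0.20 SE). Camera gave an adjusted p of 1.04e-60 for the list, and adjusted p = 0.259 with an estimated correlation. Of 10 GABAergic genes 4 fell (5 adjusted over the list alone), among them Dlx2, Dlx5 (-1.51) and Dlx1 (-1.39). The GABA-synthesis gene Gad1 did not pass the test, at -0.13 ± 0.23 (SE). The list median was -0.89 with a camera adjusted p of 7.57e-07, and adjusted p = 0.391 with an estimated correlation. Of 49 hypothalamic patterning factors 5 fell, among them Dlx2 and Meis2 (-1.11), while 7 were higher and 11 lower adjusted over the list alone. The median of that list was 0.26 and its mean 0.41, both opposite in sign to camera's direction, and the list was not called (adjusted p 0.430). Of 20 progenitor genes only the Notch ligand Dll1 fell (-0.90), with 3 higher and 3 lower adjusted over the list alone, and the list was not called (adjusted p 0.624). Of 17 mural and mesenchymal genes 0 were called over all genes by edgeR and 3 were lower adjusted over the list alone, with 70.7 ± 3.81 CPM (SD, n = 3) in negative and 41.7 ± 3.19 CPM in positive cells for Fbln1. The mural list had a median of -0.76 and a camera adjusted p of 0.0108, and adjusted p = 0.699 with an estimated correlation. Without mCherry-negative replicate 1 it was 0.137, and without mCherry-positive replicate 2 it was 0.199.

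Of 22 astrocyte genes Gfap rose (1.45 ± 0.21 SE), with 9 higher adjusted over the list alone; the median was 0.63 and camera's adjusted p 2.33e-07, and adjusted p = 0.391 with an estimated correlation. Of 19 ependymal and ciliated genes Cfap65, a protein of motile cilia, rose (2.53), with 11 higher adjusted over the list alone. That list had a median of 1.42 and a camera adjusted p of 9.73e-08, and adjusted p = 0.391 with an estimated correlation. Of 15 listed Hcrt neuron markers 11 passed the filter, and Hcrt itself, Lhx9, Qrfp and Hmx2 did not. Among the 11 the imprinted zinc-finger gene Plagl1 rose (1.61), with 7 higher and 1 lower adjusted over the list alone. The marker median was 1.61 and camera's adjusted p 1.67e-05, and adjusted p = 0.391 with an estimated correlation. Plagl1 was called higher in EGFP-positive cells as well. Plagl1, Peg3 and Dlk1 are also on the imprinted list, and Scg2 and Pcsk1 on the dense-core vesicle list, so these lists are not independent. Of 32 imprinted genes Zim1 (2.84), Zdbf2 (1.45) and Plagl1 rose, with 11 higher adjusted over the list alone. The imprinted list had a median of 0.64 and a camera adjusted p of 6.10e-05, and adjusted p = 0.391 with an estimated correlation. Of 20 dense-core vesicle genes 0 were called over all genes and 8 were higher adjusted over the list alone. Cpe, a peptide-processing enzyme, stood at 5689 ± 1908 against 3379.96 ± 1095 CPM (SD, n = 3). The vesicle list had a median of 1.14 and a camera adjusted p of 2.08e-06, and adjusted p = 0.391 with an estimated correlation. Beside these genes, the hormone genes Pomc, Tshb and Cga, chosen after their values were seen, stood at 2109, 71.1 and 62.8 CPM in mCherry-positive replicate 2 and at 4251, 673 and 436 CPM in replicate 3, but at 3.92, 0.123 and 2.45 CPM in replicate 1. Of 34 neuronal channel and receptor genes Gabbr2, a GABA-B receptor subunit (0.94), and Adra2a, an alpha-2 adrenergic receptor (1.78), rose, with 4 higher adjusted over the list alone. Their median was 0.43 and camera's adjusted p 0.0258, and adjusted p = 0.756 with an estimated correlation. Without mCherry-negative replicate 1, mCherry-positive replicate 2 or mCherry-positive replicate 3 the adjusted p of the channel list was 0.137, 0.418 and 0.361.

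In 8 mitochondrially encoded genes, beside the higher mitochondrial share of the mCherry-positive libraries, 0 were called over all genes and 4 were higher adjusted over the list alone. Their median was 0.64 and camera's adjusted p 8.00e-04, and adjusted p = 0.554 with an estimated correlation. Of 20 microglia and macrophage genes 0 were called over all genes and 3 were higher adjusted over the list alone, with a median of 1.49. Camera gave 5.73e-04 for them, and adjusted p = 0.722 with an estimated correlation; without mCherry-positive replicate 1 the adjusted p was 0.616. Of 22 other neuropeptide genes 0 were called and 1 was higher adjusted over the list alone (median 1.08, camera adjusted p 0.0220, and adjusted p = 0.756 with an estimated correlation). The neuropeptide list was lost without mCherry-negative replicate 1 (0.378), mCherry-positive replicate 2 (0.0997) or mCherry-positive replicate 3 (0.231). It includes Pomc, which was high in mCherry-positive replicates 2 and 3 and not in 1. Of 28 interferon genes 0 were called over all genes or adjusted over the list alone (median 0.52, camera adjusted p 0.0159, and adjusted p = 0.794 with an estimated correlation). Without mCherry-positive replicate 1 the interferon list turned downward with an adjusted p of 0.991, and without mCherry-negative replicate 3 its adjusted p was 0.373. Of 20 p53 genes 0 were called over all genes and 2 were higher adjusted over the list alone (median 0.47, camera adjusted p 0.00175, and adjusted p = 0.391 with an estimated correlation). Of 24 glycolysis and hypoxia genes 0 were called either way (median 0.32, camera adjusted p 0.0111, and adjusted p = 0.699 with an estimated correlation). The glycolysis list was lost without mCherry-negative replicate 1 (0.371) or mCherry-positive replicate 2 (0.112). Of 19 clock genes 0 were called over all genes and 3 were higher adjusted over the list alone (median 0.55, camera adjusted p 3.87e-04, and adjusted p = 0.391 with an estimated correlation). Camera called none of these lists: MCH neuron markers (adjusted p 0.624), pan-neuronal genes (0.624), glutamatergic genes (0.506), oligodendrocyte genes (0.429), endothelial genes (0.550), immediate early genes (0.407), unfolded protein response (0.931) and cholesterol synthesis (0.246). Among these, adjustment over the list alone gave 1 higher pan-neuronal, 1 higher glutamatergic, and 1 higher and 2 lower oligodendrocyte genes.

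In all, camera called 16 of the 26 lists, 13 upward and 3 downward, and 0 with an estimated correlation; fry called 1, the cell cycle list (adjusted p 0.0310). The count of called genes rested on single libraries. Without mCherry-negative replicate 1, mCherry-negative replicate 2 or mCherry-positive replicate 3, edgeR called 0 genes, with 3673, 2764 and 2439 at an unadjusted p under 0.05, 1766, 1083 and 824 called by DESeq2 and 0 by limma-voom. Without mCherry-positive replicate 2 it called 16, and without mCherry-negative replicate 3 it called 29. All 208 genes kept their sign in all 6 left-out fits, but they were picked on these same libraries, so this says little on stability.

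The EGFP comparison asked how cells with an active MCH reporter differ from cells sorted as EGFP-negative. EGFP-positive cells held more transcripts of astrocytes, as in Gfap at 6776 ± 203 against 3209.9 ± 60.3 CPM (SD, n = 3). They held fewer transcripts of oligodendrocytes, as in the myelin gene Mbp at 376 ± 8.79 against 1268 ± 28.5 CPM (SD, n = 3). Pomc was lower in EGFP-positive cells, at 28.9 ± 8.80 against 326 ± 49.97 CPM (SD, n = 3). Col1a1, a fibrillar collagen, was also lower, at 11.7 ± 2.46 against 108 ± 13.8 CPM (SD, n = 3). Ttr, the thyroid hormone carrier transthyretin, was higher, at 146 ± 21.0 against 22.8 ± 2.22 CPM (SD, n = 3).

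Of 16326 genes tested, 1468 were higher and 1154 lower in EGFP-positive cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 8 named rises were Kdr, a receptor of vascular endothelial growth factor (log2 fold change 3.19 ± 0.37 SE), Ttr (2.67 ± 0.15 SE), the matrix gene Thbs2 (2.25), Cnmd (2.13), Cd109 (2.08), the fatty acid receptor Cd36 (2.06), Pmch (1.99) and the cholecystokinin receptor Cckbr (1.96). The 8 named falls were the proteoglycan gene Dcn (-3.79 ± 0.21 SE), Pomc (-3.50 ± 0.23 SE), Col1a1 (-3.20), Col3a1 (-3.17), the chemokine gene Cxcl12 (-3.01), Aldh1a2, a retinoic acid synthesis enzyme (-2.92), the complement gene C1qb (-2.78) and Pllp (-2.72). All 3 positive libraries lay beyond all 3 negative libraries in these 16 genes. On GRCm38, Kdr (ENSMUSG00000062960) lies on chromosome 5 from 75932827 to 75978458, Ttr (ENSMUSG00000061808) on chromosome 18 from 20665280 to 20674321, Dcn (ENSMUSG00000019929) on chromosome 10 from 97479609 to 97518143 and Pomc (ENSMUSG00000020660) on chromosome 12 from 3954951 to 3960642.

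In EGFP-positive cells 17 of 20 oligodendrocyte genes fell (18 adjusted over the list alone), among them Bcas1 (-2.18), the lineage factor Sox10 (-2.28), Mbp (-1.75 ± 0.08 SE) and Mag (-2.49), with a list median of -1.80. Camera's adjusted p was 1.29e-53, and adjusted p = 0.00181 with an estimated correlation. Of 22 astrocyte genes 17 rose and S100b fell (18 higher and 1 lower adjusted over the list alone), among them Gfap (1.08 ± 0.06 SE), Mlc1 (0.91), Clu (0.87) and the glycolytic enzyme gene Aldoc (0.74). The astrocyte median was 0.83 with a camera adjusted p of 2.71e-17, and adjusted p = 0.00860 with an estimated correlation. Of 20 microglia and macrophage genes 15 fell and 2 rose (16 lower and 3 higher adjusted over the list alone), with a median of -2.73; the falls included Lyz2 (-1.61), C1qa (-2.75) and Ctss (-2.74). Cx3cr1 fell to 0.0956 CPM from 3.61 CPM, and the rises were the microglial receptor gene P2ry12 and Cd14. Camera's adjusted p for microglia was 6.96e-18, and adjusted p = 0.0183 with an estimated correlation. Of 15 mural and mesenchymal genes 8 fell, among them the matrix genes Dcn, Col1a1, Col3a1 and Vtn (-1.91), and 4 rose: the contractile genes Acta2, Tagln and Myl9, and Pdgfrb (8 lower and 5 higher adjusted over the list alone). The mural median was -1.83 with a camera adjusted p of 2.37e-06, and adjusted p = 0.0223 with an estimated correlation. Of 20 ependymal and ciliated genes 14 rose (18 adjusted over the list alone), among them Rsph1 (1.01), Foxj1, the regulator of motile cilia (0.89), and Pifo (1.09). The ependymal median was 1.01 with a camera adjusted p of 1.05e-09, and adjusted p = 0.0125 with an estimated correlation.

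Of 27 pan-neuronal genes 18 fell in EGFP-positive cells (21 adjusted over the list alone), among them the growth cone gene Gap43 (-1.01), Celsr3 (-1.19) and Mapt, which encodes tau (-0.76). The median was -0.64 and camera's adjusted p 1.07e-11, and adjusted p = 0.0125 with an estimated correlation. Of 32 neuronal channel and receptor genes 10 fell and 1 rose (11 lower and 1 higher adjusted over the list alone), with falls of Kcnd2 (-0.94), the calcium channel gene Cacna1b (-1.48) and Grin1 (-1.03). The channel median was -0.56 with a camera adjusted p of 2.16e-04, and adjusted p = 0.0335 with an estimated correlation. Of 20 dense-core vesicle genes 7 fell and 2 rose (10 lower and 2 higher adjusted over the list alone): Chga (-1.50) and Scg2 (-1.32) fell, and Cpe rose (0.89). The vesicle median was -0.40 with a camera adjusted p of 0.00211, and adjusted p = 0.0579 with an estimated correlation. Of 9 glutamatergic genes 3 fell (4 adjusted over the list alone), among them the glutamate transporter gene Slc1a1 (-2.06); the median was -0.58 and camera's adjusted p 0.00299, and adjusted p = 0.0701 with an estimated correlation. Of 10 GABAergic genes 4 fell and 1 rose (7 lower and 1 higher adjusted over the list alone), among the falls the vesicular GABA transporter gene Slc32a1 (-1.25). That list had a median of -0.38 and a camera adjusted p of 0.0156, and adjusted p = 0.0915 with an estimated correlation. Of 21 other neuropeptide genes 3 fell and 1 rose (6 lower and 2 higher adjusted over the list alone), with a fall of Pomc and a rise of Pdyn, which encodes dynorphins (1.42 ± 0.23 SE). The neuropeptide median was -0.65 with a camera adjusted p of 0.0158, and adjusted p = 0.325 with an estimated correlation.

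Of 28 interferon genes 19 rose and Mx2 fell (20 higher and 1 lower adjusted over the list alone), among them Ifit3 (1.41 ± 0.12 SE), Ifit1 (1.54) and the chemokine gene Cxcl10 (1.14). The interferon median was 0.77 with a camera adjusted p of 6.57e-12, and adjusted p = 0.0113 with an estimated correlation. Of 20 p53 genes 8 rose (8 higher and 1 lower adjusted over the list alone), among them Ddit4l (1.04) and the death receptor gene Fas (0.99). That list had a median of 0.60 and a camera adjusted p of 5.91e-04, and adjusted p = 0.0457 with an estimated correlation. Of 8 mitochondrially encoded genes 7 fell (7 adjusted over the list alone), such as mt-Nd1 (-0.55), beside the lower mitochondrial share and lower share of reads outside features in EGFP-positive libraries. Their median was -0.57 and camera's adjusted p 3.97e-04, and adjusted p = 0.237 with an estimated correlation. Of 20 progenitor genes 6 rose (8 higher and 1 lower adjusted over the list alone), such as the glutamate transporter gene Slc1a3 (1.34); the median was 0.44 and camera's adjusted p 0.0136, and adjusted p = 0.0892 with an estimated correlation. Of 16 listed endothelial genes only 6 passed the filter, 4 of them with a positive log2 fold change. Among the 6, Kdr and Slco1c1 (1.36) rose (2 adjusted over the list alone), so the list rests on few genes. It had a median of 1.04 and a camera adjusted p of 0.0104, and adjusted p = 0.0892 with an estimated correlation. Without EGFP-negative replicate 3 the endothelial adjusted p was 0.131, and without EGFP-positive replicate 2 it was 0.0648. Of 32 imprinted genes 6 fell and 2 rose (9 lower and 3 higher adjusted over the list alone): the growth factor gene Igf2 fell (-2.25) and Mest rose (0.96). The imprinted median was -0.25 with a camera adjusted p of 0.0227, and adjusted p = 0.0915 with an estimated correlation.

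Of 20 immediate early genes 7 rose (7 adjusted over the list alone), such as Zfp36 (0.69), with a median of 0.35 and a camera adjusted p of 0.00299, and adjusted p = 0.325 with an estimated correlation. Of 26 genes of the unfolded protein and integrated stress response 8 rose and 1 fell (10 higher and 2 lower adjusted over the list alone), such as the cystine transporter gene Slc7a11 (1.14). That list had a median of 0.19 and a camera adjusted p of 0.0154, and adjusted p = 0.0892 with an estimated correlation. Of 19 clock genes 4 rose (5 adjusted over the list alone), with a median of 0.37 and a camera adjusted p of 0.00474, and adjusted p = 0.125 with an estimated correlation. Camera did not call the cell cycle list, of whose 40 genes only Cdc20 fell (-0.40, adjusted p 0.0366 by edgeR; 0 adjusted over the list alone), at a camera adjusted p of 0.101. It did not call the Hcrt neuron markers (adjusted p 0.662), where 2 of 11 rose and Scg2 fell (3 higher and 1 lower adjusted over the list alone), and whose median of 0.06 became -0.04 with no scaling. It did not call the MCH neuron markers (adjusted p 0.647), of whose 12 genes only Pmch rose (1 adjusted over the list alone), with a median of -0.26. It did not call the patterning factors (adjusted p 0.0501), where 3 rose and 8 fell of 47 (4 higher and 8 lower adjusted over the list alone), with falls of Nkx2-2 (-1.70) and Gsx1 (-0.998) and a rise of Fezf2 (1.02). Cholesterol synthesis (adjusted p 0.0564; 3 of 24 higher, 4 higher and 1 lower adjusted over the list alone) and glycolysis and hypoxia (adjusted p 0.154; 1 higher and 2 lower of 24, the same adjusted over the list alone) were not called either.

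Camera called 20 of the 26 lists in the EGFP comparison, and 9 held with an estimated correlation. Without scaling beyond library size the median log2 fold change of all genes moved by -0.11, and 39.7% of called genes were higher instead of 56.0%. Without EGFP-positive replicate 1 edgeR called 5244 genes, against 1141 without EGFP-positive replicate 2. It called 1287, 1137 and 1340 without EGFP-negative replicates 1, 2 and 3, and 801 with all 12 samples in 1 fit. All 2622 genes kept their sign in the left-out fits, but they were picked on these same libraries, so this says little on stability.

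**Figure D2:**
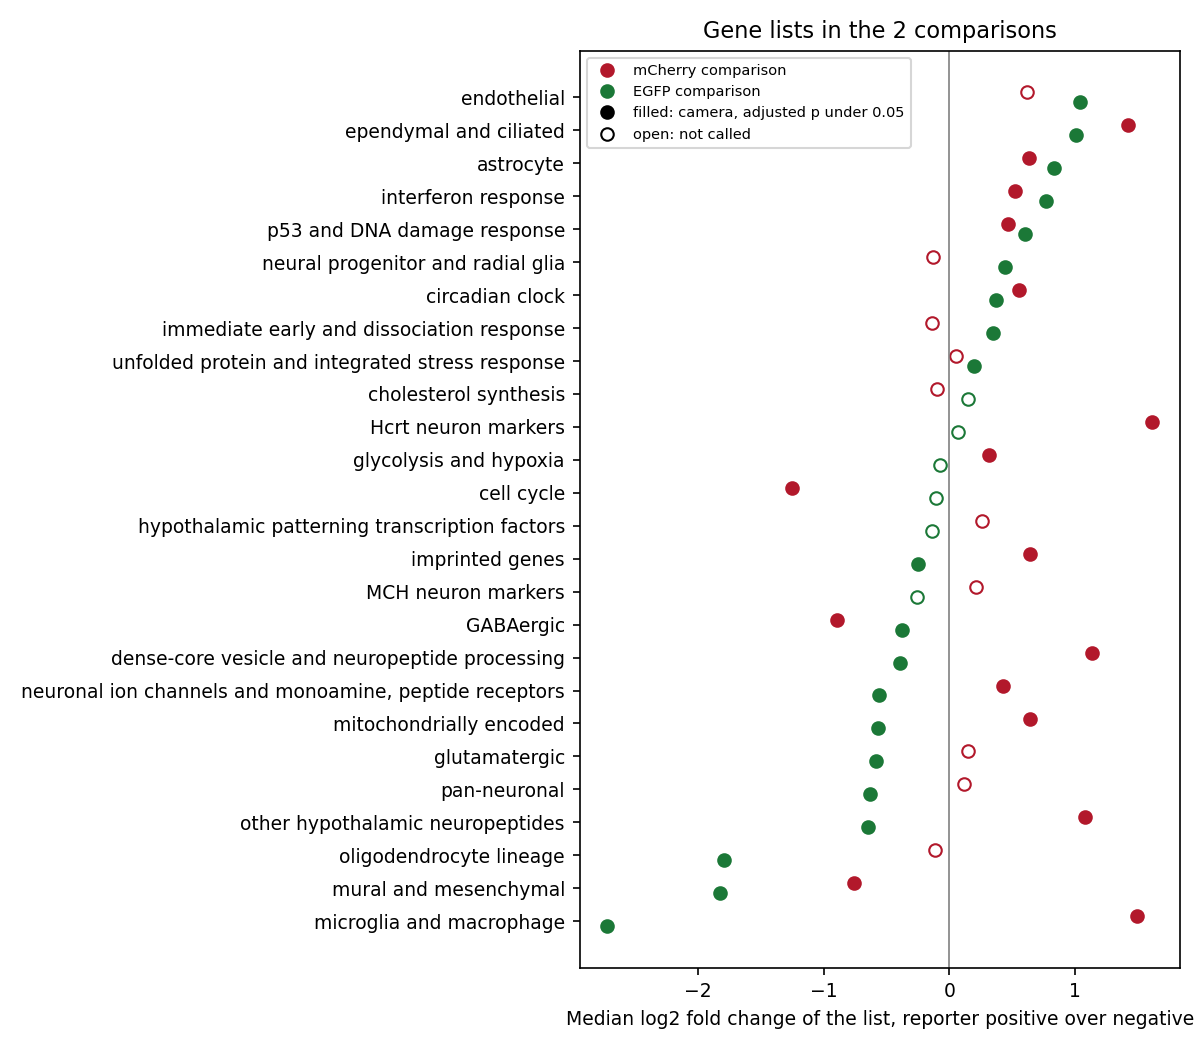
Median log2 fold change of each of the 26 gene lists (horizontal axis, reporter-positive over reporter-negative) in the mCherry (red) and EGFP (green) comparisons. Filled points have a camera adjusted p under 0.05; the cell cycle list lies at -1.25 for mCherry and -0.11 for EGFP, and the oligodendrocyte list at -0.12 and -1.80.

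The difference between both effects asked for which genes positive and negative cells differed otherwise in the Hcrt sort than in the MCH sort. Reporter, virus and RNA input changed together between the sorts, so a difference cannot be assigned to any of them. Oligodendrocyte genes were set apart: the myelin gene Mbp stood at 1609 ± 416 CPM in mCherry-positive and 1229.9 ± 191 in mCherry-negative cells (SD, n = 3), but at 387 ± 10.4 in EGFP-positive and 1290.3 ± 24.96 in EGFP-negative cells (SD, n = 3). Cell cycle genes were set apart the other way: Cdca8 stood at 28.1 ± 2.75 against 90.6 ± 6.17 CPM in the mCherry sort and at 88.7 ± 8.94 against 96.9 ± 1.34 CPM in the EGFP sort (SD, n = 3). The peptide-vesicle gene Scg2 stood at 246 ± 157 against 58.4 ± 35.0 CPM in the mCherry sort and at 24.6 ± 1.40 against 60.7 ± 5.45 CPM in the EGFP sort (SD, n = 3). The difference for Scg2 lost its call without mCherry-positive replicate 2 or 3 (adjusted p 0.0797 and 0.0898 by edgeR).

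Of 18063 genes tested, the difference, mCherry effect minus EGFP effect, was positive for 160 and negative for 101 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 6 named positive genes were Oacyl, the microglial and macrophage genes Mpeg1, Cybb, Cx3cr1, Csf1r and Tmem119, all with few reads in EGFP-positive cells. Csf1r stood at 52.8 ± 78.7 CPM in mCherry-positive and 0.347 ± 0.461 CPM in EGFP-positive cells (SD, n = 3), at an adjusted p of 0.0285 by edgeR and of 0.0109 without mCherry-positive replicate 1, the library that held most of its reads. Cx3cr1 stood at 31.3 ± 39.5 and 0.0988 ± 0.0772 CPM in the same groups (SD, n = 3). Oacyl lost its call without mCherry-positive replicate 3, at an adjusted p of 0.0887 by edgeR. The 6 named negative genes were Gsx2 (-2.11), Acta2 (-2.10), the carbonic anhydrase gene Car3 (-2.03 ± 0.30 SE), the DNA glycosylase gene Neil3 (-1.90), Tagln (-1.85) and the replication gene Pclaf (-1.77). Gsx2 lost its call without mCherry-positive replicate 2 or 3 (adjusted p 0.0797 and 0.0758 by edgeR), and Acta2 without replicate 2 (0.0666).

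For cell cycle genes the difference was negative in 19 of 40 (38 adjusted over the list alone), with a median of -1.19 and a camera adjusted p of 1.17e-48, and adjusted p = 0.0205 with an estimated correlation. Examples were Cdca8 (-1.56 ± 0.19 SE), Rrm2 (-1.70), Cdk1 (-1.39) and Cdc20 (-1.17). For oligodendrocyte genes it was positive in 12 of 20 (14 higher and 1 lower adjusted over the list alone), with a median of 1.52 and a camera adjusted p of 2.76e-30, and adjusted p = 0.0140 with an estimated correlation. Examples were Mbp (2.12 ± 0.24 SE), Enpp6 (2.59) and Mag (2.72). For microglia and macrophage genes it was positive in 5 of 22 (18 adjusted over the list alone), with a camera adjusted p of 8.15e-17, and adjusted p = 0.168 with an estimated correlation. For mitochondrially encoded genes, beside mitochondrial shares that moved in opposite directions in the sorts, it was positive in 4 of 8 (7 adjusted over the list alone), at a median of 1.05 and a camera adjusted p of 4.04e-10, and adjusted p = 0.164 with an estimated correlation. For dense-core vesicle genes it was positive in Baiap3 (4.19) and Scg2 (3.37) of 20 (12 adjusted over the list alone), at a median of 1.53 and a camera adjusted p of 6.70e-09, and adjusted p = 0.164 with an estimated correlation. Beside them the hormone genes Pomc, Tshb and Cga, high in mCherry-positive replicates 2 and 3 and not in 1, had log2 differences of 7.87, 8.10 and 6.52 that did not pass the test (adjusted p 0.0744, 0.103 and 0.0658 by edgeR). For neuronal channel and receptor genes it was positive in 1 of 36 (9 adjusted over the list alone), at a median of 0.98 and a camera adjusted p of 1.42e-07, and adjusted p = 0.168 with an estimated correlation.

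For imprinted genes the difference was positive in Zim1 (3.84) and Rian (1.92) of 32 (12 higher and 1 lower adjusted over the list alone), at a camera adjusted p of 1.76e-07, and adjusted p = 0.164 with an estimated correlation. For pan-neuronal genes it was positive in Nefl (2.60) of 27 (6 adjusted over the list alone), at a camera adjusted p of 3.06e-06, and adjusted p = 0.386 with an estimated correlation. For glutamatergic genes it was positive in Slc17a6 (4.22) and Slc1a1 (2.01) of 9 (3 adjusted over the list alone), at a camera adjusted p of 7.90e-04, and adjusted p = 0.190 with an estimated correlation. For Hcrt neuron markers it was positive in Scg2 and Cacna2d1 (2.17) of 12 (5 higher and 1 lower adjusted over the list alone), at a camera adjusted p of 0.00275, and adjusted p = 0.168 with an estimated correlation. Without mCherry-positive replicate 2 or 3 the edgeR calls of Scg2, Cacna2d1 (adjusted p 0.0819 and 0.0722) and Nefl (0.0685 and 0.0522) were lost. For GABAergic genes the difference was negative in Dlx2 (-1.65) of 10 (4 adjusted over the list alone), at a camera adjusted p of 0.00224, and adjusted p = 0.320 with an estimated correlation. For immediate early genes it was negative in Socs3 (-1.03) of 20 (4 adjusted over the list alone), at a camera adjusted p of 3.55e-04, and adjusted p = 0.168 with an estimated correlation. Camera also called 4 lists in which edgeR called 0 genes. Upward were other neuropeptides (0 of 25, 1 adjusted over the list alone, camera adjusted p 6.93e-04, and adjusted p = 0.386 with an estimated correlation) and glycolysis (0 of 24, 0 adjusted over the list alone, camera adjusted p 0.00151, and adjusted p = 0.320 with an estimated correlation). Downward were progenitor genes (0 of 20, 2 adjusted over the list alone, camera adjusted p 0.00570, and adjusted p = 0.164 with an estimated correlation) and cholesterol synthesis (0 of 24, 0 adjusted over the list alone, camera adjusted p 0.00599, and adjusted p = 0.505 with an estimated correlation). The neuropeptide list includes Pomc, which was high in mCherry-positive replicates 2 and 3 and not in 1. Without mCherry-negative replicate 1 the camera adjusted p was 0.100 for glycolysis and 0.0605 for cholesterol synthesis. Without mCherry-positive replicate 3 it was 0.210 for cholesterol synthesis.

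Camera did not call the difference for the MCH markers (adjusted p 0.187), patterning factors (0.448), astrocyte (0.197), endothelial (0.583), mural (0.227), ependymal (0.187), interferon (0.187), p53 (0.607), unfolded protein response (0.112) and clock (0.540) lists. The mural median of 0.60 was opposite in sign to camera's direction, and its 4 called genes, Tagln, Myl9 (-1.32), Fbln1 (-1.07) and Acta2, were all negative (1 higher and 4 lower adjusted over the list alone). The endothelial median was -0.25 but its mean 0.00435, and 1 endothelial gene was lower adjusted over the list alone. Of 55 patterning factors 1 was positive, and Dlx2 and Meis2 (-0.92) were negative (6 higher and 7 lower adjusted over the list alone). Meis2 lost its call without mCherry-positive replicate 1, 2 or 3 (adjusted p 0.0534, 0.0949 and 0.05965 by edgeR). Of 22 astrocyte genes Aldh1l1 was negative (-1.21; 1 higher and 2 lower adjusted over the list alone), and the median of -0.04 became 0.12 with no scaling. The p53 median of -0.16 became 0.00765 with no scaling. Camera called 16 lists, 11 upward and 5 downward, and 2 with an estimated correlation. With no scaling the median difference of all genes moved by 0.16, and 79.7% of called genes were positive instead of 61.3%. Without single libraries edgeR called 27 to 591 genes: 591 without mCherry-positive replicate 1, 72 without mCherry-negative replicate 2, 163 without mCherry-positive replicate 3, 172 without mCherry-positive replicate 2, 151, 43 and 114 without EGFP-positive replicates 1, 2 and 3, and 40, 35 and 27 without EGFP-negative replicates 1, 2 and 3.

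**Figure D3:**
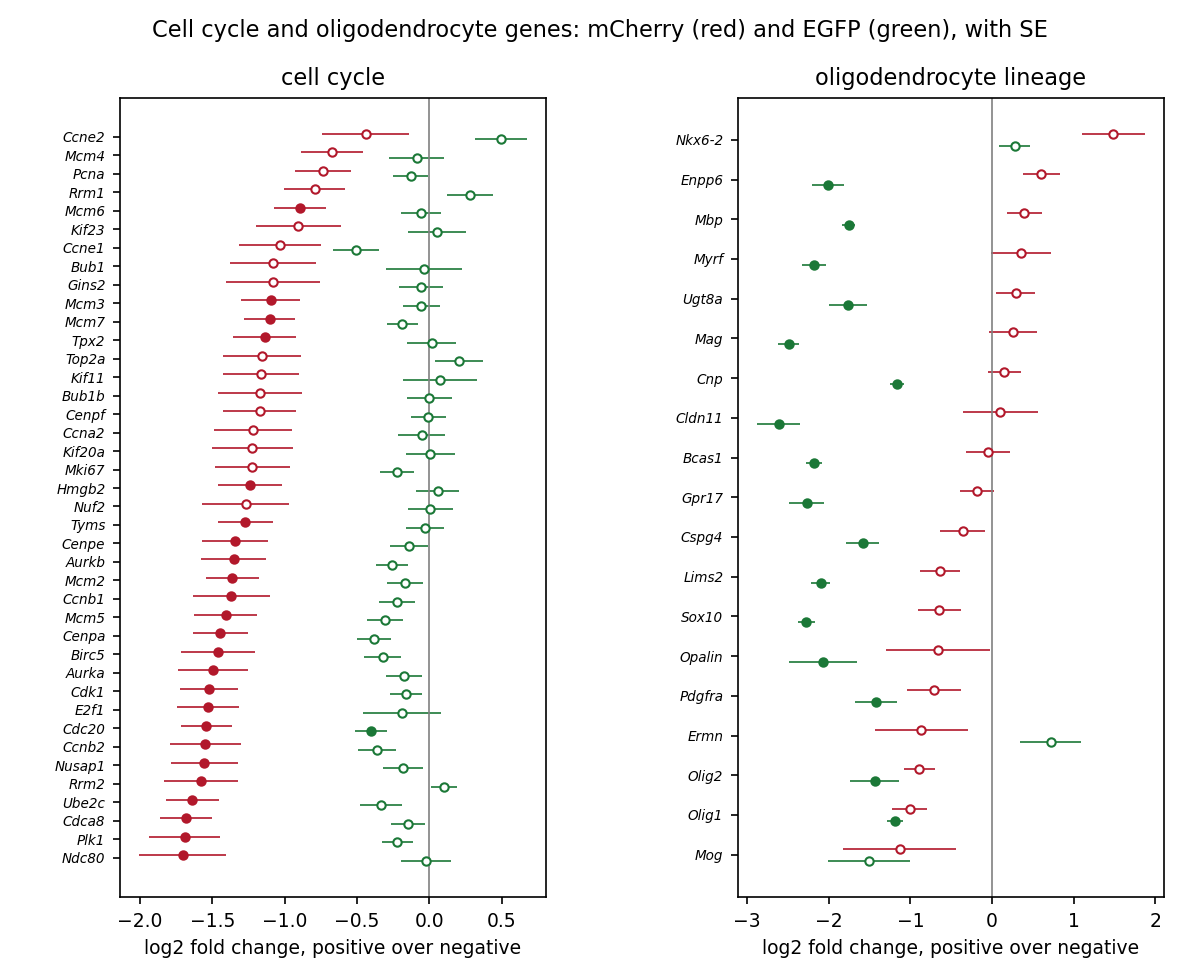
Log2 fold change of cell cycle genes (left) and oligodendrocyte genes (right), reporter-positive over reporter-negative, in the mCherry (red) and EGFP (green) comparisons; bars are SE and filled points have an adjusted p under 0.05 by edgeR. Of the 40 cell cycle genes 24 are called lower for mCherry and 1 for EGFP, and of the oligodendrocyte genes shown none is called for mCherry and most are called lower for EGFP.

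The last comparison asked how far both sorts share changes, on 15995 genes tested in both fits, which share no libraries. Genes higher in both sorts included Gfap, Frzb, the cilia gene Cfap65, Plagl1, Crb1 and Cckbr, and genes lower in both included Dlx1, Dlx5, Cdc20, Dll3 and Igfbpl1. In all, 62 genes were higher in both against 8.31 expected from the list sizes, an odds ratio of 22.2 (Fisher's exact test p 3.73e-43, a description, since genes are not independent). Lower in both were 12 genes against 8.15 expected (Fisher's exact test p 0.197). Mal2 and Spint1 were higher in mCherry-positive and lower in EGFP-positive cells, against 6.51 expected, and Car3 was the reverse, against 10.4 expected. Across genes, log2 fold changes of both comparisons correlated at a Pearson r of 0.236 and a Spearman rho of 0.345, and genes are not independent replicates. Of 205 genes called for mCherry and tested in both, 180 had the same sign for EGFP (87.8%), against 63.3% of all 15995 genes and 75.5% of the genes called for EGFP. Without mCherry-negative replicate 1, mCherry-negative replicate 2 or mCherry-positive replicate 3 the shared count of 74 was 0, as no mCherry gene was called there by edgeR; it was 38 without mCherry-positive replicate 1, 11 without mCherry-positive replicate 2, 12 without mCherry-negative replicate 3, 43 without EGFP-positive replicate 2, and 44, 43 and 47 without EGFP-negative replicates 1, 2 and 3. The r was 0.131 without mCherry-negative replicate 3 and 0.129 without EGFP-positive replicate 3.

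**Figure D4:**
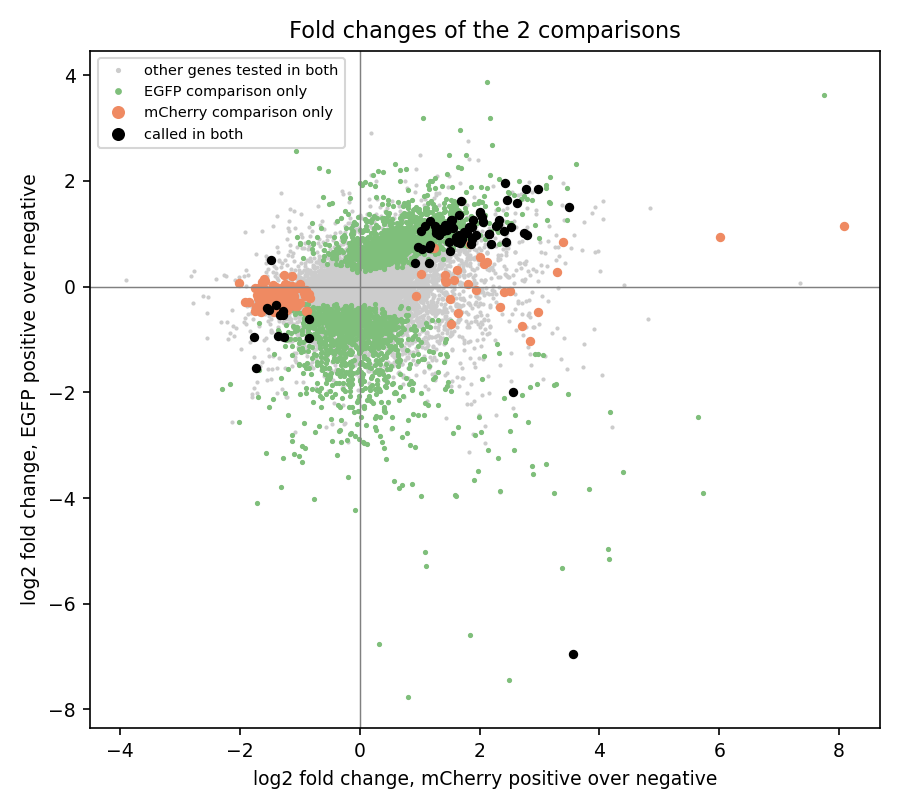
Log2 fold change of 15995 genes in the mCherry comparison (horizontal) and the EGFP comparison (vertical), each reporter-positive over reporter-negative. Black points are called in both comparisons, orange points in mCherry alone and green points in EGFP alone; 62 of the black points are higher in both.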

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

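The tests for the Hcrt level, for single libraries and vector dilution in the cell cycle genes, and for Pomc neurons were chosen after the results were seen, and so were the list tests for the difference and the ratio of Hcrt rates without single libraries.

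The effect of the sort differed between the reporters for 261 genes and 16 lists, by edgeR's and camera's test of the difference itself; with an estimated correlation 2 of the lists held, and with fry 7 were called. Other splits of the samples were tried for each count. For mCherry, 10 splits are too few for a share under 0.05; the real split called 208 genes (1 split of 10 as large, the real one) and the highest other 1. For EGFP they are too few as well, with 2622 genes for the real split (1 as large) and 0 as the highest other. For the difference, 100 of 200 distinct splits were drawn, and 4 gave as many genes as the real one, which is included. The highest other split called 399 genes, and the other 3 as large all kept the true EGFP labels and mixed the mCherry labels, so they do not test the EGFP labels. By the limit set beforehand, this count argues only narrowly against chance assignment of all labels. Splits that mix the EGFP labels put the EGFP effect into the spread, which can lower their counts. The count therefore does not show that the effects differ between the reporters. For the mCherry labels, the difference count does not stand apart from the splits that mixed them.

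The positive log2 differences, mCherry effect minus EGFP effect, included 5.52 for Tmem119, whose size rests on few reads in EGFP-positive cells and on mCherry-positive replicate 1 (25.6 CPM, against 2.59 and 6.26 in replicates 2 and 3). Positive differences with a median of at most 3 reads in a group, too few for a fold, had adjusted p by edgeR of 0.0109 for Cx3cr1, 0.0237 for Mpeg1, 0.0285 for Csf1r, 0.0327 for Oacyl, 0.0406 for Itgam and 0.0420 for Cybb. Cybb stood at 57.8, 2.499 and 1.28 CPM in mCherry-positive replicates 1, 2 and 3. Positive too were Slc17a6 (4.22), Baiap3 (4.19), Zim1 (3.84), Scg2 (3.37), Mag (2.72), Nefl (2.60), Enpp6 (2.59), Cacna2d1 (2.17), Mbp (2.12), Slc1a1 (2.01) and Rian (1.92). The mitochondrial genes mt-Nd4 (1.35), mt-Cytb (1.05), mt-Nd5 (1.04) and mt-Co1 (1.02) were positive. Negative were Gsx2 (-2.11), Acta2 (-2.10), Car3 (-2.03), Neil3 (-1.90), Tagln (-1.85), Pclaf (-1.77), Rrm2 (-1.70), Dlx2 (-1.65), Cdca8 (-1.56), Cdk1 (-1.39), Myl9 (-1.32), Aldh1l1 (-1.21), Cdc20 (-1.17), Fbln1 (-1.07), Socs3 (-1.03) and Meis2 (-0.92). Calls lost without mCherry-positive replicate 2 or without replicate 3 included those of Oacyl, Scg2, Cacna2d1, Nefl, Gsx2, Acta2 and Meis2.

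Hcrt stood near the detection limit in all libraries, mCherry-positive ones included. Reads lost to an overlapping gene are argued against by the annotation, in which 0% of the exonic bases of Hcrt lie inside another gene. Too little depth to see Hcrt at the level Pmch has in EGFP-positive cells is argued against by the upper 95% bound, at most 0.714 CPM in any mCherry-positive library against 17.2 CPM. A reporter active in cells that do not make Hcrt stays open: the ratio of Hcrt rates, positive over negative, was 1.82, with an interval from 0.837 to 4.17 that neither shows nor excludes enrichment, 0.960 (0.316 to 2.71) without mCherry-positive replicate 3 and 2.41 (1.08 to 5.66) without replicate 2. Whether the cells make Hcrt protein, or make it at a later age, was not tested.

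Cell cycle genes were lower in mCherry-positive cells in 24 of 40 by edgeR, with a camera adjusted p of 1.04e-60 for the list, and adjusted p = 0.259 with an estimated correlation. A single library as the cause of the lower median is argued against by the fits without each library, in which it was at most -1.11, although edgeR called 0 genes in 3 of these 6 fits (2439 to 3673 at an unadjusted p under 0.05, 824 to 1766 called by DESeq2 and 0 by limma-voom). A bias of gene length or expression level is argued against by 10000 random lists matched on both, of which 0 had a median as low, the lowest being -0.37. Loss of vector by dilution in dividing cells, which may occur with adeno-associated virus and not with an integrating lentivirus, stays open: the median difference between the reporters was -1.19, as it would need, but the virus and the reporter cannot be told apart here. A biological difference between Hcrt-reporter cells and the others stays open too, untested.

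Pomc, Tshb and Cga, of which the last pair was chosen after its values were seen, were lower in EGFP-positive cells. Pomc neurons alone would leave unexplained the falls of Tshb (-2.47, adjusted p 3.21e-04 by edgeR) and Cga (-2.38, adjusted p 4.84e-04). Those neurons are not known to make these hormone subunits. Both falls belong to the pattern itself, though, so this was not an independent test. Pituitary cells in the dissected tissue, which no sort gate named in the labels would remove from the negative cells, are a candidate source: of 14 other pituitary genes, none in the 26 lists, 6 were measured with a median of -1.74, and Lhx3 and Gnrhr fell. The most abundant of the 6, Gh at a mean of 13.8 CPM, did not pass the test (-0.30, adjusted p 0.307 by edgeR). The others stood near 1 CPM or below. In the mCherry sort the pituitary genes tested had positive log2 fold changes except Prl (-1.52), and none passed the test by edgeR. There, Gh stood at 0.0817, 75.6 and 152 CPM in mCherry-positive replicates 1, 2 and 3, and Pou1f1 at 0, 5.41 and 12.2 CPM. Transcripts of such genes were thus not confined to reporter-negative cells. Which of these genes hypothalamic cells also express was not tested.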

How the results depend on the processing

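The list tests for the difference were chosen after seeing the data. Among counts and correlations none turned sign, but the mCherry interferon list turned downward without mCherry-positive replicate 1, and most called genes were higher instead of lower for mCherry with no filter (62.3% against 45.2%) and lower instead of higher for EGFP with no scaling (39.7% against 56.0%). In mCherry, 208 called genes became 343 with the replicate block, 778 with no filter, 458 with the stricter filter, 1476 with DESeq2, 1712 with all 12 samples in 1 fit and 0 at an adjusted p under 0.01 by edgeR (3233 at an unadjusted p under 0.05). In EGFP, 2622 became 801 with all 12 samples and 1047 at an adjusted p under 0.01. For the difference, 261 became 675 with no filter, 894 with DESeq2 and 22 at 0.01. The fit of all 12 samples, which raised the mCherry count and lowered the EGFP count, also gave the difference. With an estimated correlation, called lists fell to 0 for mCherry, 9 for EGFP and 2 for the difference, and with fry to 1 for mCherry and 7 for the difference. Genes called in both comparisons, 74, became 143 with the block, 270 with no filter, 171 with the stricter filter, 548 with DESeq2 and 203 with all 12 samples; the correlation of 0.236 became 0.0332 with no filter, 0.406 with the stricter filter and 0.0817 with all 12 samples. Leaving out 1 library at a time gave 0 to 212 genes for mCherry, 1137 to 5244 for EGFP and 27 to 591 for the difference; 12 to 17, 19 to 22 and 15 to 20 lists; 0 to 104 shared genes; and correlations of 0.129 to 0.262. Of named called genes, none of 32 for mCherry, 43 of 99 for EGFP and 6 of 41 for the difference kept the call at an adjusted p under 0.05 in every alternative fit; in those fits, 157 of the 164 lost mCherry calls came with a left-out library, which also leaves fewer samples. Apart from these constructions, the cause was not tested. At this depth the ratio of Hcrt rates had an interval of 0.837 to 4.17 and moved from 0.960 to 2.48 with the library left out.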

Other observations

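All genes in this part were chosen after their values were seen. Pomc, Tshb and Cga, genes of pituitary and hypothalamic hormones, differed widely between mCherry-positive libraries. Pomc stood at 3.92, 2109 and 4251 CPM in mCherry-positive replicates 1, 2 and 3, and at 3.69, 193 and 88.7 CPM in the mCherry-negative ones. Tshb stood at 0.123, 71.1 and 673 CPM in the mCherry-positive replicates and Cga at 2.45, 62.8 and 436 CPM. Neither Pomc, Tshb nor Cga was called in the mCherry comparison by edgeR, with adjusted p of 0.218, 0.187 and 0.159.

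Microglial genes stood apart in the other mCherry-positive library. Cx3cr1 stood at 76.1, 3.57 and 15.1 CPM in mCherry-positive replicates 1, 2 and 3, and Csf1r at 143, 8.19 and 7.36 CPM. In mCherry-negative libraries Csf1r stood at 3.06 to 4.38 CPM. Oacyl, which is not on the microglia list, went the other way, at 0.204, 14.2 and 60.6 CPM in mCherry-positive replicates 1, 2 and 3. Of the microglial genes, P2ry12 stood at 3.70 to 4.30 CPM in EGFP-positive libraries and at 1.40 to 1.84 CPM in EGFP-negative libraries, opposite to Cx3cr1.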
